A study of Mus musculus with 6 samples.

How the data were processed

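RNA sequencing of skin from E16.5 mouse embryos (Mus musculus) was analysed for 6 samples, 3 labelled WT and 3 labelled Irf6_KO. The source label of all 6 samples, WT included, also carries the words kinase dead and names no kinase, so the groups were taken from the genotype label alone. Replicates were numbered within each group in the order of their records, and these numbers only name the samples. Per the labels' protocols, total RNA was column-purified with DNase digestion, poly(A) libraries were prepared with a TruSeq RNA v2 kit, and single-end reads were produced on an Illumina HiSeq instrument. Nothing in the labels says whether the samples of a group came from separate embryos or litters, so p-values measure only the spread between these samples, which may be technical.

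The deposited files give, per the file headers, a count column with the number of reads aligning uniquely to each gene model, and these raw counts are the values tested. The same files give a second column of size-factor-adjusted RPKM (nRPKM) made by the authors, per the file headers. GSNAP and the genome build GRCm38 are named in the submitters' processing notes, without a version for GSNAP. The counting tool, the annotation release and the strand setting are not given in the sources used here. For genes with at least 200 counts, the ratio of RPKM to count between any library and WT replicate 1 was one constant per library, equal to the inverse DESeq2 size factor of the counts (largest difference 0%). The RPKM column therefore adds no measurement to the counts and was used only for this check.

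Each file lists the same 52636 Ensembl gene identifiers, of which 52403 matched a symbol in a supplied table of mouse gene names and 233 did not. The unmatched identifiers held 0.0213 to 0.0283% of the counts and stayed in the tests without being named. Where a symbol stood for several identifiers, the one with the highest total count was used for lists and names (74 repeated symbols). Coordinates, gene types and exon overlaps come from the GENCODE M21 annotation of GRCm38 and were taken with bedtools 2.31.1 and Python 3.11.15. That release was supplied with the reference and may differ from the one behind the counts.

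Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr, which left 17811 of 52636, libraries were scaled by TMM, and the groups were compared with a quasi-likelihood F-test with robust dispersion estimates and no covariate, over all 6 libraries. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called changed at an adjusted p under 0.05. Levels are TMM-normalised CPM, given as mean ± SD over n = 3 libraries per group. Log2 fold changes are the fitted values, Irf6_KO over WT, and their standard errors (SE) are those implied by the F statistic. For a gene with no counts in any library of a group, the fitted fold depends on the prior count and is used only for ranking and for medians named as fitted. Its fold is given as "at least", computed against 3 counts over that group (0.0334 CPM in Irf6_KO and 0.0354 CPM in WT). A gene with 1 to 3 counts in a group is given with the ratio of its counts per TMM-scaled library size and a 95% counting interval. Floors and intervals cover counting error only. An exact permutation test of 3 against 3 libraries cannot go below p = 0.1, so single quantities such as the share of mitochondrial counts are given per library without a test.

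Gene lists were fixed before the data were examined: 32 lists with 644 entries and 624 different genes, of which 582 were tested. They cover the layers and programmes of the epidermis, and markers of other cell types of skin, of sex and of tissue handling. Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 32 lists. Camera compares a list with the other genes. It was repeated with the correlation estimated from the data, where its p also comes from the few residual degrees of freedom of 6 libraries. Fry was run beside it. Fry tests whether the genes of a list move one way on balance, or in either direction (mixed), without comparing them with other genes. The design, the alternatives and the rule for named genes were likewise fixed before the data were examined. The rule names Irf6, then the 12 genes with the largest fitted rise and the 12 with the largest fitted fall among changed genes with a mean of at least 5 CPM in the higher group and no overlap between the groups' libraries, leaving out symbols of unnamed gene models. It also names, for each list, up to 4 members with the smallest adjusted p under 0.05 and, where fewer than 2 passed, the 2 members with the highest mean level. It gave 134 genes.

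Alternatives were DESeq2 1.42.0, limma-voom, scaling by median-ratio (RLE) factors or by library size only, no low-count filter, a filter of at least 1 CPM in 3 libraries, no robust estimation, a test against a fold of 1.5, 1 surrogate variable (sva 3.50.0), removal of the sex-linked, muscle and erythroid genes, and each library left out in turn. Chosen after seeing the data were the map of the epidermal differentiation complex, the families of genes that share a symbol stem, and the close look at counts without Irf6_KO replicate 1. The edgeR step was tested on counts simulated from the means, library sizes and gene-wise dispersions of the 6 libraries with 200 genes changed (17625 genes tested). It recovered 66% of the 50 genes changed 1.5-fold, 84% of those changed 2-fold, 92% of those changed 4-fold and 98% of those changed 8-fold, and 11.9% of its calls were false. Over 5 further draws, a mean of 4.66% of calls were false with dispersions on the fitted trend and 7.57% with gene-wise dispersions. The adjusted p can thus be somewhat too small for genes whose spread departs from the trend. With 200 genes changed the adjusted threshold is stricter than with the 5946 called in the data, so these shares need not hold there.

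Reads of 50 bp that align to several places are not in the counts, so members of near-identical families (Lce1, Sprr2, Hba and Hbb genes) can be undercounted or can share reads. Exons of 11 of the 134 named genes overlap exons of another gene with over 10% as many reads over the 6 libraries. These genes are Irf6, Sh2d5, Sprr2a1, Smpd3, Elovl1, Tm7sf2, Fdft1, Tjp3, Irf9, Ripk1 and Dusp1. Without a stated strand setting, their reads cannot be told from those of the partner in the overlap. Figures were drawn with matplotlib 3.10.9.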

Results

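Poly(A) RNA from skin of E16.5 mouse embryos was sequenced in 6 libraries, 3 of the genotype WT and 3 of the genotype Irf6_KO, to compare WT skin with skin carrying a knockout of Irf6, a transcription factor of the interferon regulatory factor family known to act in keratinocyte differentiation. The libraries held 26931783 to 31330856 counted reads, and 24145 to 24705 genes had counts in each. On the first principal component of log2 CPM, with 86.1% of the variance, the WT libraries lay between -70.6 and -68.6 and the Irf6_KO libraries between 68.1 and 73.0. Pearson correlations across genes were 0.988 to 0.995 within a group and 0.919 to 0.925 between groups. No pair of libraries was alike to within sampling noise, since the smallest chi-square per degree of freedom within a group was 3.41. Irf6_KO replicate 1 stood apart from the other knockouts on the second component (4.97% of the variance, at -32.7 against 15.7 and 18.1). The third component held nearly as much (4.24%) and set Irf6_KO replicates 2 and 3 apart from each other (-27.6 and 25.8). Irf6_KO replicate 1 correlated at 0.988 with each of these, which correlated at 0.990 with each other. Irf6_KO replicate 1 was also the only library with Xist above 7 counts (73367), with 5 counts of Ddx3y against 1768 to 2974 in the other 5 libraries. By these counts it came from a female and the other 5 from males, all WT libraries included, so sex was not balanced between the genotypes. Mitochondrial genes took 1.18 to 1.19% of counts in WT and 1.40 to 1.74% in Irf6_KO.

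Irf6 itself (ENSMUSG00000026638, GRCm38 chromosome 1, 193153111 to 193172023, plus strand) was lower in every Irf6_KO library than in every WT library. Its level was 169 ± 15.6 CPM in WT and 41.0 ± 9.68 CPM in Irf6_KO, a log2 fold change of -2.04 (SE 0.17) with adjusted p = 6.13e-05 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment, as for all genes below). The single libraries read 181, 151 and 175 CPM in WT and 30.6, 42.5 and 49.8 CPM in Irf6_KO. Counts per gene do not show from which exons the remaining reads came. Part of an Irf6 exon is shared with A130010J15Rik, which had 10.4% as many reads in WT and 49.4% in Irf6_KO and did not pass the test (log2 fold change 0.20, SE 0.08, adjusted p = 0.0767).

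Between the genotypes 5946 of 17811 genes tested changed, 2956 higher and 2990 lower in Irf6_KO. The large changes were mostly falls. Of the changed genes, 497 were higher and 1167 were lower by more than 2-fold, and 78 were higher and 402 lower by more than 8-fold. In 60 of the lower genes no Irf6_KO library held a count. The groups' libraries did not overlap for 8537 genes (47.9%, where chance gives 10%). With library size alone as scaling, the median log2 fold change over all genes moved by 0.11 and the split became 4848 higher and 2457 lower (66.4% higher, against 49.7% with TMM), so small changes are relative to the TMM scale. Without WT replicate 3, 1959 genes were higher.

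The 12 largest falls that the naming rule gave were 9 genes of the late cornified envelope family, Kprp, Krtap15 and Slc46a2. Kprp, a keratinocyte proline-rich protein, read 622 ± 26.0 CPM in WT and had no counts in Irf6_KO, which is at least 18663-fold lower (adjusted p = 8.16e-10). Slc46a2, a solute carrier, fell from 82.2 ± 6.44 CPM to no counts (at least 2474-fold, adjusted p = 4.02e-09). Krtap15, a keratin-associated protein, had no counts in Irf6_KO either, but varied between WT libraries (91.8 ± 40.1 CPM, at least 2719-fold, adjusted p = 0.0116) and did not pass without WT replicate 1, where its adjusted p was the highest of 14 alternatives (range 3.29e-24 to 0.0838). Among the 12 largest rises were the stress keratins Krt6b, Krt16 and Krt6a, the small proline-rich gene Sprr2a3 and S100a9, a subunit of calprotectin. The others were C2cd4b, the receptor chain gene Il20ra, the potassium channel gene Kcnh1, the protease gene Tmprss11b, Sh2d5, the serpin Serpinb3d and the transporter gene Slc16a14. C2cd4b had no counts in WT and 5.13 ± 0.929 CPM in Irf6_KO (at least 144-fold higher, adjusted p = 2.56e-06). Il20ra rose 95.2-fold, from 0.134 ± 0.0864 to 12.8 ± 3.31 CPM (adjusted p = 3.67e-07), Kcnh1 83.6-fold (0.403 to 34.8 CPM), Tmprss11b 78.7-fold (0.143 to 11.5 CPM), Serpinb3d 28.3-fold (0.252 to 7.16 CPM) and Slc16a14 28.0-fold (2.64 to 73.7 CPM). Kcnh1 lies near Irf6, on chromosome 1 at 192190774 to 192510159, against a start of Irf6 at 193153111. A local effect of the altered allele on Kcnh1 therefore cannot be told from a response to the loss of Irf6. Sh2d5 read 24.3 ± 13.8 CPM in Irf6_KO, 30.2-fold above WT, but its exons overlap those of Kif17, which had 91.2% as many reads in WT and 38.3% in Irf6_KO and rose as well (log2 fold change 3.66), so its own rise is uncertain.

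**Figure D1:**
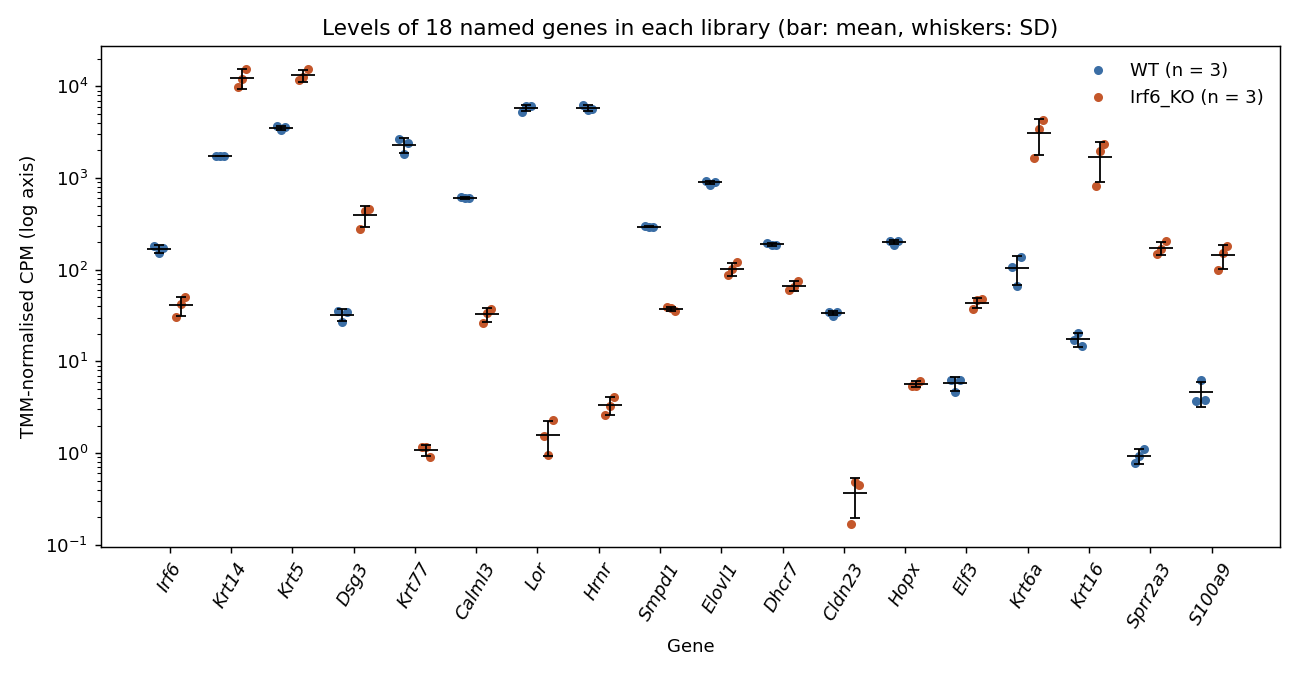
TMM-normalised CPM (log axis) of 18 genes named by the rule, one point per library, with WT in blue and Irf6_KO in orange (n = 3 each), bars at the mean and whiskers of 1 SD. Irf6 falls from 169 to 41.0 CPM, the basal keratins Krt14 and Krt5 rise, the differentiation genes from Krt77 to Hopx fall, and Krt6a, Krt16, Sprr2a3 and S100a9 rise.

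Transcripts of the cornified envelope, the protein shell of the outermost epidermal cells, were far lower in Irf6_KO. In the list of its structural genes, 33 of 34 tested members fell and 1 did not pass, with a median log2 fold change of -4.46 (camera adjusted p = 1.27e-24, adjusted p = 0.329 with an estimated correlation). Lor, which encodes loricrin, fell from 5824 ± 491 to 1.60 ± 0.662 CPM, a log2 fold change of -11.84 (SE 0.27) (adjusted p = 1.54e-09). Hrnr, which encodes hornerin, fell from 5856 ± 417 to 3.33 ± 0.746 CPM (adjusted p = 2.26e-10), and the keratin gene Krt80 fell 39.5-fold, from 236 ± 16.8 to 5.97 ± 1.07 CPM. All 18 tested members of the late cornified envelope family fell (camera adjusted p = 6.02e-28, adjusted p = 0.220 with an estimated correlation), and 12 of them had no counts in any Irf6_KO library. The median log2 fold change of this family was -13.96 as fitted and -12.07 with the genes at 0 set to their bound. Lce1a1 read 662 ± 55.7 CPM in WT and was at least 19904-fold lower in Irf6_KO, and Lce1l was at least 3692-fold lower. Lce1a2, Lce1d, Lce1b, Lce1c, Lce1i and Lce1g were lower by at least 2712-fold to at least 12035-fold. Lce1m fell from 1391 ± 225 CPM to 4 counts over the 3 Irf6_KO libraries together, all of them in replicate 3. Lce6a had 2 counts in Irf6_KO against 10413 in WT, a ratio of 5521 (95% counting interval 1528 to 45598), and Lce1e and Lce1f had 1 each, ratios of 8562 (95% counting interval 1536 to 338234) and 8279 (95% counting interval 1486 to 327050.0). Lce1 genes resemble one another closely, so single members are uncertain. Both lists together took 3.11 to 3.34% of all counts in WT and 0.154 to 0.214% in Irf6_KO.

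The small proline-rich (Sprr) family, which encodes cross-linked envelope precursors, moved in both directions. Of 13 tested members 4 rose, 4 fell and 5 did not pass, and the list did not stand apart from other genes (camera adjusted p = 0.667). Sprr2a3 rose 184-fold, from 0.940 ± 0.174 to 173 ± 28.9 CPM (adjusted p = 3.19e-09), and Sprr2b rose from 0.0984 ± 0.0837 to 3.43 ± 0.759 CPM (adjusted p = 7.16e-06). Sprr2a1 had no counts in WT and 69 in Irf6_KO (at least 21.7-fold higher, adjusted p = 4.33e-04), though it shares exons with Sprr2a2 and the Sprr2a genes are near copies. Sprr3 fell from 60.1 ± 19.5 CPM to 3 counts, a ratio of 1780.2 (95% counting interval 609 to 8635) (adjusted p = 1.24e-05). The number of lower members rests on single libraries. It was 1 without WT replicate 1 or WT replicate 3 and 2 without WT replicate 2, without Irf6_KO replicate 3 or with no low-count filter. With at least 1 CPM required in 3 libraries, 2 members were higher.

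These families lie in the epidermal differentiation complex, and the tested genes from S100a1 to S100a10 on GRCm38 chromosome 3, 90511034 to 93564643, were mapped as a region chosen after seeing the data. Of 68 tested genes 43 fell (44 adjusted over the region alone), 8 rose and 17 did not pass. The median log2 fold change was -3.34 (camera p = 1.62e-17, p = 0.0231 with an estimated correlation, both from limma and unadjusted, for a single region). Of the 68 genes 42 also belong to one of the lists.

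**Figure D2:**
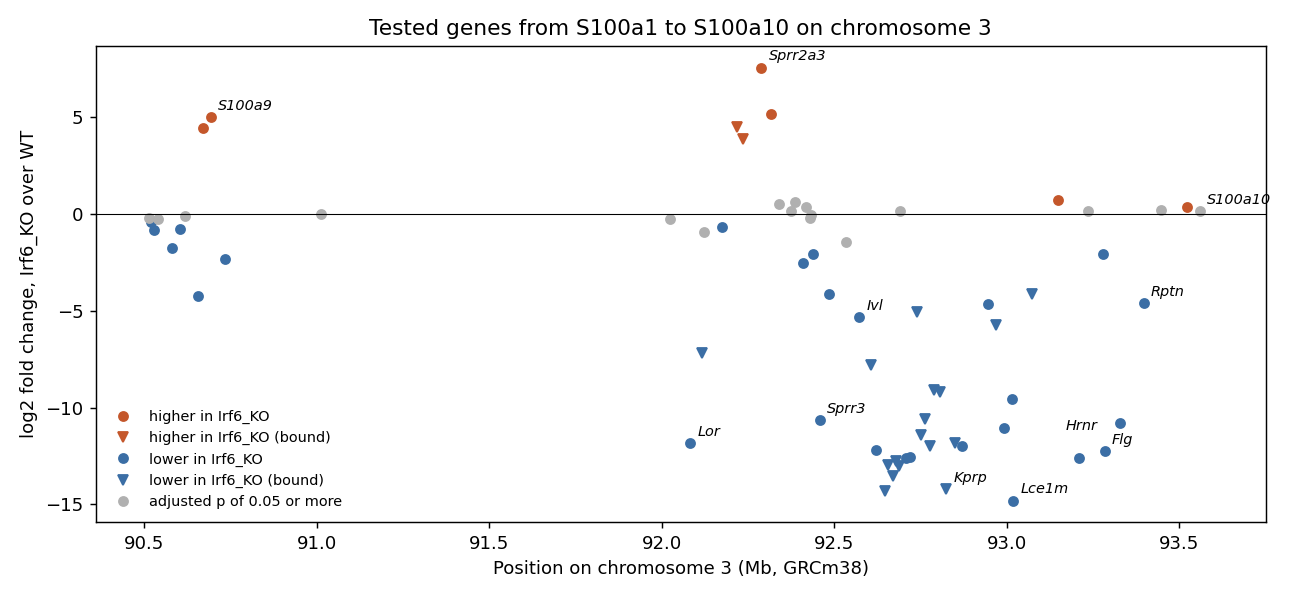
Log2 fold change (Irf6_KO over WT, n = 3 each) of the 68 tested genes from S100a1 to S100a10 against their position in Mb on chromosome 3 (GRCm38), with triangles for genes at 0 counts in one group, drawn at their bound. The 43 lower genes include all tested Lce genes and Lor, and the 8 higher genes include S100a9 near the left end and Sprr2a3.

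Suprabasal and basal keratinocyte genes moved in opposite directions. In the spinous and early differentiation list 16 of 19 tested members fell, 1 rose and 2 did not pass (median log2 fold change -2.67, camera adjusted p = 1.44e-12, adjusted p = 0.382 with an estimated correlation). Krt77, an embryonic suprabasal keratin, fell from 2309 ± 421 to 1.08 ± 0.154 CPM (adjusted p = 3.90e-10) and Krt78 fell 726-fold, from 165 ± 6.53 to 0.222 ± 0.0482 CPM. The far more abundant suprabasal keratin genes Krt10 and Krt1, named after their values were seen, fell less and stayed high. Krt10 fell from 26812 ± 2510 to 3436 ± 334 CPM and Krt1 from 24124 ± 2358 to 6057 ± 705 CPM. Calml3, a calmodulin-like protein, fell from 608 ± 10.4 to 32.7 ± 5.70 CPM, and Ptgs1, a cyclooxygenase, from 134 ± 14.8 to 26.8 ± 2.22 CPM (adjusted p = 6.44e-08). The member that rose was the receptor gene Notch3 (log2 fold change 0.68 (SE 0.09)). In the basal keratinocyte list 12 of 18 tested members rose, 1 fell and 5 did not pass (median 0.91, camera adjusted p = 5.70e-05, adjusted p = 0.585 with an estimated correlation). Krt14 rose 7.19-fold, from 1729 ± 5.40 to 12426 ± 2948 CPM (adjusted p = 7.97e-07), and its partner keratin Krt5 3.73-fold, from 3551 ± 164 to 13245 ± 1956 CPM. Cdh3, which encodes P-cadherin, rose by 1.23 on the log2 scale and the integrin gene Itga6 by 1.18 (adjusted p = 2.13e-05). The member that fell, named after its value was seen, was the cyclin gene Ccnd2, and 2 members fell without Irf6_KO replicate 3. Irf6_KO replicate 1 lay below replicates 2 and 3 by a median of 0.27 on the log2 scale over the basal list.

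Desmosome and adherens junction genes, which join keratinocytes, gave 8 higher members of 17 (9 adjusted over the list alone), 2 lower and 7 that did not pass. The list's median log2 fold change was 0.35 (camera adjusted p = 0.00964, adjusted p = 0.809 with an estimated correlation, and fry adjusted p = 0.0570). Dsg3, the desmoglein of the lower epidermal layers, rose from 32.5 ± 5.02 to 391 ± 99.2 CPM (log2 fold change 3.59 (SE 0.23), adjusted p = 3.05e-05). Dsc3, Nectin1 and Dsg2 rose by 0.96, 1.04 and 0.74 on the log2 scale (adjusted p = 0.00115, 1.88e-04 and 1.28e-04). The lower members numbered 1 without any one WT replicate, without Irf6_KO replicate 2 or with no low-count filter.

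Genes of the lipid barrier, whose enzymes make the ceramides and long-chain fatty acids of the outer epidermis, fell as a group. Of 33 tested members 31 fell, 1 rose and 1 did not pass, with a median log2 fold change of -2.59 (camera adjusted p = 1.14e-23, adjusted p = 0.329 with an estimated correlation). Smpd1, which encodes acid sphingomyelinase, fell from 296 ± 5.67 to 37.7 ± 1.87 CPM, a log2 fold change of -2.97 (SE 0.07) (adjusted p = 1.28e-09). Pnpla1, an enzyme of acylceramide synthesis, fell 12.6-fold, from 127 ± 9.69 to 10.1 ± 1.86 CPM, and Elovl1, a fatty acid elongase, 8.70-fold, from 895 ± 43.7 to 103 ± 16.9 CPM. Smpd3 fell 367-fold, with 69 counts left in Irf6_KO, and its exons overlap those of Prmt7, which had 0.184 times as many reads in WT and 73.8 times in Irf6_KO. Elovl1 overlaps Cdc20, which had 7.03% as many reads in WT and 63.7% in Irf6_KO. The cholesterol synthesis list changed less, with 16 of 23 members lower (18 adjusted over the list alone) and 7 that did not pass (median -0.46, camera adjusted p = 2.83e-06, adjusted p = 0.659 with an estimated correlation). Dhcr7, which catalyses the last step to cholesterol, fell from 189 ± 6.15 to 66.5 ± 8.27 CPM (adjusted p = 8.88e-07). Pmvk fell by 0.97 on the log2 scale (adjusted p = 1.30e-05). Tm7sf2 and Fdft1 also fell (log2 fold changes -1.31 and -0.73), but the genes that overlap their exons, Vps51 and Ctsb, had 1.66 times as many reads in WT and 3.69 times in Irf6_KO, and 15.9 times as many reads in WT and 39.0 times in Irf6_KO.

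Tight junction genes, which seal the upper living layer, gave 12 lower, 3 higher and 8 that did not pass out of 23 (median log2 fold change -0.43, camera adjusted p = 0.00934, adjusted p = 0.623 with an estimated correlation). The claudin gene Cldn23 fell 90.2-fold, from 33.5 ± 1.68 to 0.366 ± 0.172 CPM (adjusted p = 5.31e-09). Cgn, which encodes cingulin, fell 14.6-fold, from 77.4 ± 10.3 to 5.30 ± 0.293 CPM, and Ocln, which encodes occludin, 5.52-fold, from 23.9 ± 3.77 to 4.32 ± 1.02 CPM. Tjp3 fell 15.4-fold, and its exons overlap those of Apba3, which had 1.03 times as many reads in WT and 15.7 times in Irf6_KO. The higher members numbered 1 without WT replicate 2 or without Irf6_KO replicate 2. In the list of periderm and simple epithelium genes, named for the embryonic cover layer of the skin, 9 of 17 members fell, 5 rose (6 adjusted over the list alone) and 3 did not pass. Its median was -2.52, and the list did not pass against other genes (camera adjusted p = 0.0834, adjusted p = 0.809 with an estimated correlation), although it did with library size as the only scaling (lowest of 8 alternatives, range 0.0137 to 0.124). By fry, which compares a list with no other genes, its members moved down on balance (adjusted p = 0.00367). Krt23 fell from 341 ± 29.4 to 0.336 ± 0.113 CPM (adjusted p = 1.70e-10), Krt13 from 302 ± 58.6 to 7.38 ± 2.62 CPM, Krt8 from 6.64 ± 1.31 to 0.999 ± 0.199 CPM, and Gabrp, a GABA receptor subunit, from 8.03 ± 0.722 to 0.112 ± 0.0545 CPM. The list also holds Krt6a and Krt6b, which rose.

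Alarm and stress genes of keratinocytes split into a rising and a falling set. Of 26 tested members 12 rose (13 adjusted over the list alone), 9 fell and 5 did not pass. The median log2 fold change was 1.01 while the mean was -0.12, and camera gave the direction up (adjusted p = 0.414) where fry gave down (adjusted p = 0.0806), neither past the threshold. Krt6b rose 246-fold, from 6.44 ± 1.85 to 1585 ± 653 CPM (adjusted p = 8.21e-05), Krt16 97.4-fold, from a mean of 17.5 to 1705 CPM, Krt6a 30.0-fold, from 104 ± 35.8 to 3122 ± 1325 CPM, and S100a9 31.3-fold, from 4.59 ± 1.42 to 144 ± 42.3 CPM. Genes of the interleukin-36 group fell. Il1f6 and Il1f8, cytokines of this group, fell from 43.6 ± 1.46 CPM to 1 count (ratio 3919.5 (95% counting interval 703 to 154854)) and from 37.8 ± 4.78 to 0.157 ± 0.108 CPM (adjusted p = 5.31e-09). Il1f9 fell from 238 ± 7.76 to 19.9 ± 4.21 CPM, and Il1f5, which encodes the receptor antagonist, 101-fold, from 385 ± 5.92 to 3.80 ± 0.273 CPM. The 12 risers were lower in Irf6_KO replicate 1 than in replicates 2 and 3 by a median of 0.77 on the log2 scale, and 16 members rose without that library.

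Interferon-stimulated genes showed no common direction, with 2 higher, 4 lower and 20 that did not pass out of 26 (median -0.10, positive with library size as the only scaling, camera adjusted p = 0.646). Stat1, a signal transducer of interferon receptors, rose from 20.4 ± 1.43 to 46.0 ± 6.11 CPM (adjusted p = 1.99e-05), and Irf9 by 0.36 on the log2 scale (adjusted p = 0.00411). Irf9 shares exons with Rnf31, which had 1.08 times as many reads in WT and 1.02 times in Irf6_KO. Rnf31 rose as well (log2 fold change 0.26, adjusted p = 0.0302), so the rise of Irf9 itself is uncertain. The antiviral genes Mx1 and Rsad2 fell from 4.82 ± 0.629 to 0.872 ± 0.203 CPM and from 3.94 ± 0.799 to 1.91 ± 0.0764 CPM. Of 12 genes of the interferon regulatory factor and receptor-interacting kinase families 5 rose (6 adjusted over the list alone), 1 fell and 6 did not pass (median 0.34, camera adjusted p = 0.0834, fry adjusted p = 0.00791). Ripk4, a kinase known to act with IRF6 in epidermal differentiation, rose from 64.9 ± 4.77 to 126 ± 16.3 CPM, a log2 fold change of 0.96 (SE 0.10) (adjusted p = 5.12e-05). Irf2 rose by 0.37 and Ripk1 by 0.42, the latter with exons shared with Serpinb6a, which had 1.97 times as many reads in WT and 2.45 times in Irf6_KO and rose by 0.74. Ripk2 fell by 0.47 on the log2 scale (adjusted p = 0.00136).

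Epidermal transcription factors changed both ways, 12 higher (13 adjusted over the list alone), 13 lower (14 adjusted over the list alone) and 10 that did not pass of 35. The median log2 fold change was 0.14 and the mean -0.47, with camera pointing down (adjusted p = 0.719) and fry likewise (adjusted p = 0.00791). The homeodomain gene Hopx fell 35.3-fold, from 200.2 ± 11.5 to 5.67 ± 0.446 CPM (adjusted p = 1.98e-10). Prdm1, which encodes the repressor BLIMP1, fell 8.04-fold, from 115 ± 3.62 to 14.4 ± 1.46 CPM, and the ETS factor Ehf 3.63-fold, from 30.7 ± 2.28 to 8.46 ± 0.659 CPM. Another ETS factor, Elf3, rose 7.64-fold, from 5.75 ± 0.954 to 43.9 ± 5.41 CPM (adjusted p = 1.61e-07). In the Notch list of 18 genes, 5 rose, 3 fell (4 adjusted over the list alone) and 10 did not pass (median 0.05, camera adjusted p = 0.414, fry adjusted p = 0.0168), and 1 fell without WT replicate 1 or with library size as the only scaling. The ligand gene Jag1 rose from 69.3 ± 3.09 to 174 ± 25.6 CPM (adjusted p = 7.16e-06), the target gene Hes1 by 0.64, the receptor gene Notch3 by 0.68 and Maml2 by 0.62 on the log2 scale.

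Hair follicle genes were lower in part, with 11 of 24 tested members lower (12 adjusted over the list alone), 2 higher (3 adjusted over the list alone) and 11 that did not pass. The median was -0.58 (camera adjusted p = 0.00934, adjusted p = 0.329 with an estimated correlation). The signal gene Shh fell from 12.5 ± 0.580 to 4.34 ± 0.0940 CPM (adjusted p = 2.59e-06) and its receptor gene Ptch1 from 286 ± 9.83 to 152 ± 9.47 CPM. Lhx2, a transcription factor of the follicle, fell by 1.26 and Bmp2 by 1.39 on the log2 scale. The higher members numbered 1 without any one WT replicate or without Irf6_KO replicate 2, and also with limma-voom or RLE factors, and 4 with library size as the only scaling. For the 36 cell cycle genes, 34 did not pass and 2 rose (1 adjusted over the list alone), with a median of 0.00 that turned negative with RLE factors (camera adjusted p = 0.767). Without Irf6_KO replicate 1, 2 of them fell, and 1 fell by DESeq2, by limma-voom, with RLE factors, with no low-count filter and with sex-linked, muscle and erythroid genes left out. Mcm4, a subunit of the replicative helicase, rose from 116 ± 1.54 to 145 ± 8.73 CPM (adjusted p = 0.00510). Cenpe passed narrowly (adjusted p = 0.0460, range 0.0103 to 0.129 over 14 alternatives) and did not in 8 of 14 alternatives, among them DESeq2, limma-voom, RLE factors and the omission of any one library except Irf6_KO replicate 3.

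**Figure D3:**
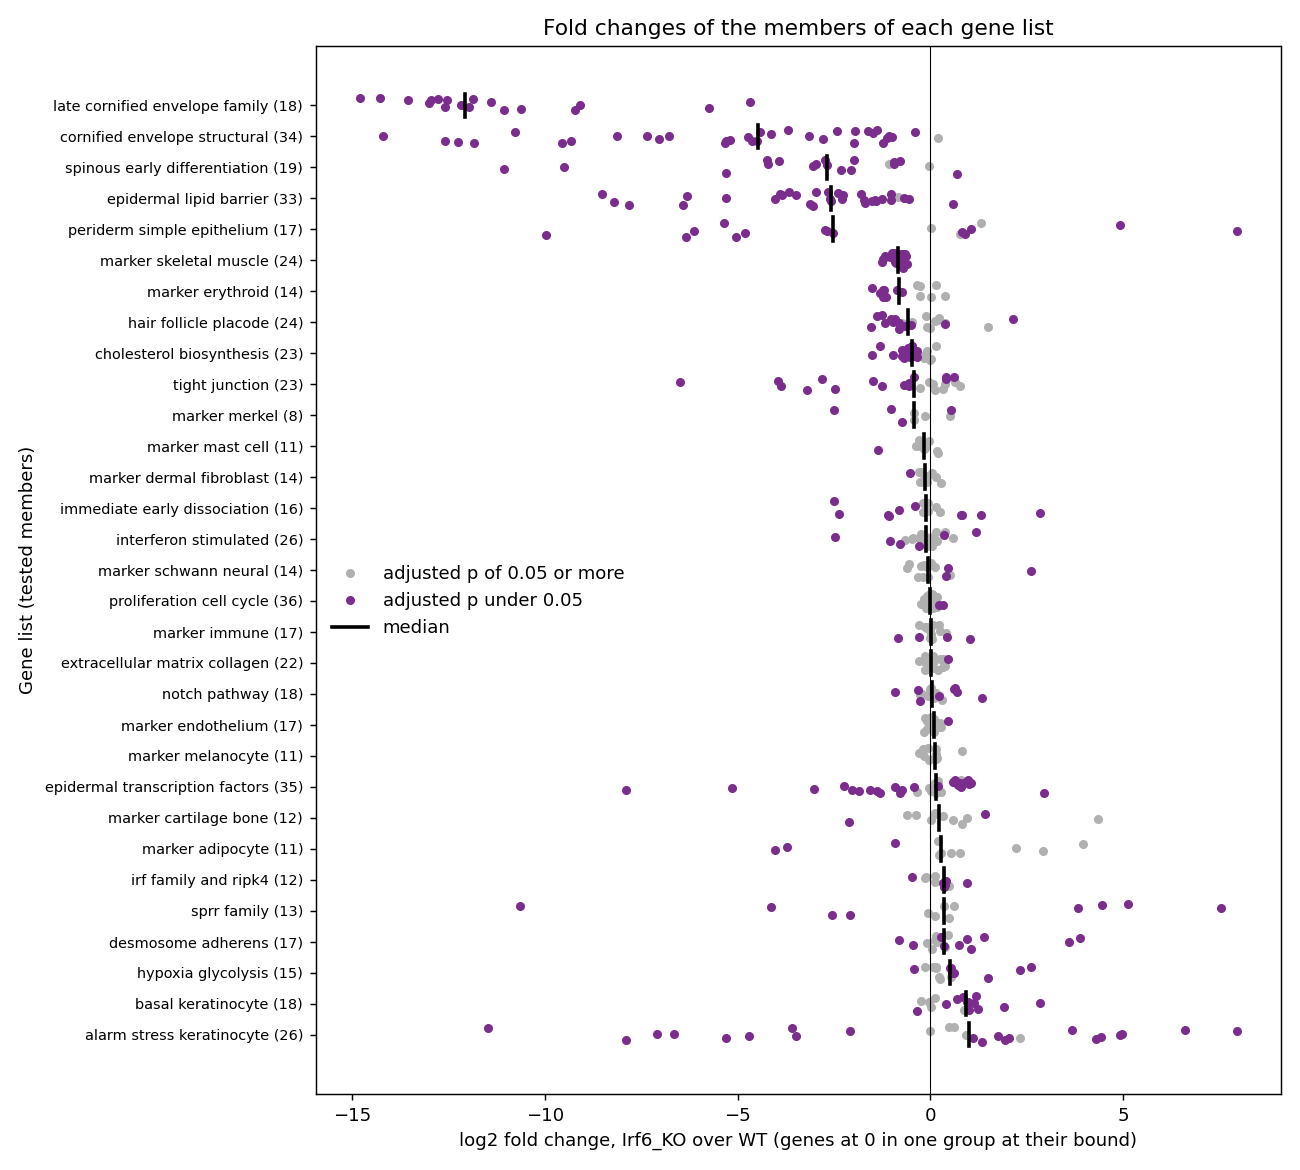
Log2 fold change (Irf6_KO over WT, n = 3 each) of every tested gene of the lists, one row per list and one point per gene, purple at an adjusted p under 0.05 and gray otherwise, with genes at 0 counts in one group at their bound. Black bars are medians, lowest for the late cornified envelope family (-12.07) and highest for the alarm list (1.01), and the list of sex-linked genes is left out.

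Among markers of other cell types, those of skeletal muscle and red cells were lower in Irf6_KO. All 24 tested muscle genes fell, none of them a member of another list, with a median log2 fold change of -0.83 and quartiles of -0.95 to -0.73 (camera adjusted p = 2.50e-11, adjusted p = 0.585 with an estimated correlation). With no low-count filter 13 of the 24 passed. The troponin genes Tnnc1, Tnni1 and Tnnt1 fell from 88.4 ± 7.53 to 38.9 ± 4.49 CPM, from 136 ± 8.31 to 73.7 ± 5.88 CPM and from 175 ± 10.1 to 73.3 ± 11.8 CPM, and the slow myosin gene Myh7 from 64.7 ± 9.50 to 27.6 ± 3.53 CPM (adjusted p = 5.77e-05). The list took 1.10 to 1.23% of counts in WT and 0.620 to 0.853% in Irf6_KO. Of 14 erythroid genes 8 fell and 6 did not pass (median -0.81, camera adjusted p = 0.00260, adjusted p = 0.659 with an estimated correlation). Hbb-bs fell from 3457 ± 329 to 1388 ± 295 CPM (adjusted p = 1.47e-04), and Hbb-bt, Hba-a1 and Hba-a2, near copies within their families, fell by 1.23, 1.21 and 1.24 on the log2 scale. Without Irf6_KO replicate 3, 1 erythroid gene rose. Hemoglobin genes took 0.530 to 0.672% of counts in WT and 0.199 to 0.320% in Irf6_KO.

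Dermal markers changed little in number. Of 14 fibroblast genes 1 fell (0 adjusted over the list alone by edgeR, with 4 lower at an unadjusted p under 0.05, 4 by DESeq2 and 1 by limma-voom) and 13 did not pass (median -0.14, camera adjusted p = 0.375). That gene, Twist2, read 158 ± 25.5 CPM in WT and 109.7 ± 18.2 CPM in Irf6_KO (adjusted p = 0.0233, range 4.49e-04 to 0.0745 over 14 alternatives) and did not pass without WT replicate 2 or 3 or without Irf6_KO replicate 2 or 3, nor with library size as the only scaling or no filter, and 3 genes fell without Irf6_KO replicate 1. By DESeq2, by limma-voom, at an unadjusted p under 0.05, with library size as the only scaling, with no low-count filter and without Irf6_KO replicate 3, 1 fibroblast gene rose. Of 22 matrix genes 1 rose, Thbs1 (from 92.9 ± 4.77 to 127 ± 17.8 CPM, adjusted p = 0.00601), and 21 did not pass (median 0.01, negative with RLE factors, camera adjusted p = 0.897). Matrix genes higher numbered 2 without Irf6_KO replicate 1 and 4 without Irf6_KO replicate 3 or with library size as the only scaling. In that omission, at an unadjusted p under 0.05, by DESeq2, by limma-voom, with RLE factors, with no filter, with no robust estimation and with sex-linked, muscle and erythroid genes left out, 1 matrix gene fell. The most abundant genes of both lists, Col3a1 and Col1a1, had log2 fold changes of -0.14 (SE 0.11) and -0.08 (SE 0.11) that did not pass (adjusted p = 0.379 and 0.641). Of 17 endothelial genes 1 rose, Flt1 (from 27.6 ± 2.73 to 38.1 ± 4.83 CPM, adjusted p = 0.00868), and 16 did not pass (median 0.10, camera adjusted p = 0.444). Cdh5 (adjusted p = 0.224) and Pecam1 (adjusted p = 0.440) had log2 fold changes of 0.20 and 0.11, and 4 endothelial genes rose without Irf6_KO replicate 3, Cdh5 among them (adjusted p range 0.00906 to 0.510 over 14 alternatives). Of 12 cartilage and bone genes 1 rose, Spp1 (from 0.725 ± 0.122 to 1.94 ± 0.627 CPM), 1 fell, Ibsp (log2 fold change -2.11 (SE 0.19)), and 10 did not pass (median 0.22, camera adjusted p = 0.813). Those counts were 3 and 2 without Irf6_KO replicate 3 and 3 and 1 by DESeq2, while 2 rose with no robust estimation and 2 fell with RLE factors and without Irf6_KO replicate 2.

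Of 11 adipocyte genes 3 fell and 8 did not pass, with a positive median (0.26) and mean (0.22) while camera pointed down (adjusted p = 0.414), as it did without Irf6_KO replicate 2 with the lowest adjusted p of 8 alternatives (range 0.00288 to 0.889), where 4 fell. Dgat2 (from 514 ± 34.7 to 31.7 ± 6.70 CPM, adjusted p = 1.27e-07) and Cebpa (from 182 ± 3.60 to 95.5 ± 14.4 CPM, adjusted p = 6.28e-05) belong also to the epidermal lists, as 3 of the 11 genes do. Ucp1 had 127 counts in WT and 10 in Irf6_KO (adjusted p = 0.00583) and did not pass by DESeq2, the highest adjusted p of 14 alternatives (range 2.64e-04 to 0.0812). Of 17 immune genes 2 rose, 2 fell (1 adjusted over the list alone) and 13 did not pass (median 0.01, negative with RLE factors, camera adjusted p = 0.846). Cd14 and Cd74 rose by 1.02 and 0.44 on the log2 scale and Itgam fell by 0.83 (adjusted p = 0.00456, 0.00460 and 5.58e-04). Cd68 fell (adjusted p = 0.0414) but did not pass with any one library left out or with library size as the only scaling (range 0.0263 to 0.202 over 14 alternatives), and 1 immune gene fell without each library except Irf6_KO replicate 1. Of 11 mast cell genes 1 fell, Mrgprb1 (from 12.4 ± 5.49 to 4.87 ± 1.36 CPM, adjusted p = 0.0241; 0 adjusted over the list alone by edgeR, 2 at an unadjusted p under 0.05, 2 by DESeq2 and 1 by limma-voom), and it did not pass without Irf6_KO replicate 1 or 2 or with no filter (range 9.04e-06 to 0.133 over 14 alternatives). The list's median was -0.18 (camera adjusted p = 0.404). The abundant mast cell genes Cpa3 and Hdc had log2 fold changes of -0.18 (SE 0.14) and -0.28 (SE 0.13) (adjusted p = 0.378 and 0.115), and Hdc passed by DESeq2, with no filter and without Irf6_KO replicate 1 (range 0.0131 to 0.358 over 14 alternatives). Without that library 2 mast cell genes fell, and without Irf6_KO replicate 2 none fell and 1 rose.

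Of 11 melanocyte genes 0 passed by edgeR, as by an unadjusted p under 0.05, DESeq2 and limma-voom, while 3 fell without Irf6_KO replicate 1 and 1 rose without Irf6_KO replicate 3 (median 0.13, camera adjusted p = 0.990). Kit and Dct had log2 fold changes of -0.03 (SE 0.12) and -0.17 (SE 0.24), and Dct was lower without Irf6_KO replicate 1 (the lowest adjusted p of 14 alternatives, range 0.0385 to 0.899). Of 14 Schwann cell genes 3 rose and 11 did not pass (median -0.07, positive with library size as the only scaling, camera pointing up with adjusted p = 0.935), and 2 fell without Irf6_KO replicate 1. Ncmap, Erbb3 and Mbp rose by 2.60, 0.39 and 0.46 on the log2 scale (adjusted p = 3.24e-04, 0.00739 and 0.0133). Of 8 Merkel cell genes 3 fell (4 adjusted over the list alone), 1 rose and 4 did not pass (median -0.43, camera adjusted p = 0.373, fry adjusted p = 2.24e-04), with 1 lower without Irf6_KO replicate 2 or 3 and none higher without WT replicate 1 or 2 or Irf6_KO replicate 1 or 2. Isl1 fell from 4.90 ± 0.644 to 2.96 ± 0.222 CPM (adjusted p = 0.00487). The calls of Chga, Insm1 and Piezo2 (adjusted p = 0.0166, 0.0481 and 0.0394) were each lost with single libraries left out (up to 0.0569, 0.186 and 0.140), Chga without Irf6_KO replicate 2 or 3, Insm1 without any library but Irf6_KO replicate 1, and Piezo2 without WT replicate 1 or 2 or Irf6_KO replicate 1 or 2. Over all alternatives their calls were lost in 3 of 13, 8 of 13 and 5 of 14. By limma-voom 2 Merkel genes fell and 0 rose, and by DESeq2 2 fell and 1 rose. Of the 4 tested sex-linked genes 0 passed by edgeR, as by an unadjusted p under 0.05, DESeq2 and limma-voom (median -0.40, camera adjusted p = 0.414). The 4 tested, Ddx3y, Eif2s3y, Kdm5d and Uty, are Y-linked, and Xist was not among them. As Irf6_KO replicate 1 alone came from a female, these tests do not show that the groups were alike in sex. Ddx3y read 73.8 ± 11.1 CPM in WT and 57.2 ± 50.3 CPM in Irf6_KO and Eif2s3y 57.1 ± 8.28 CPM in WT and 32.9 ± 28.4 CPM in Irf6_KO.

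Immediate early genes, which respond to tissue handling, gave 4 higher (5 adjusted over the list alone), 6 lower and 6 that did not pass out of 16 (median -0.12, camera adjusted p = 0.414). Socs3, a feedback inhibitor of cytokine signalling, rose 7.17-fold, from 12.5 ± 1.07 to 89.9 ± 7.89 CPM (adjusted p = 1.07e-08), while the early growth response genes Egr2 and Egr3 fell from 9.10 ± 1.30 to 1.74 ± 0.176 CPM and from 82.7 ± 6.53 to 14.6 ± 3.49 CPM. Dusp1 also fell (log2 fold change -1.08), with exons shared with Ergic1, which had 3.63 times as many reads in WT and 9.08 times in Irf6_KO. Hypoxia and glycolysis genes gave 7 higher, 1 lower and 7 that did not pass out of 15 (median 0.50, camera adjusted p = 0.0150, adjusted p = 0.809 with an estimated correlation, fry adjusted p = 0.0806), and without Irf6_KO replicate 3 the list did not pass by camera, with the highest adjusted p of 8 alternatives (range 2.59e-05 to 0.0570). The glucose transporter gene Slc2a1 rose 6.09-fold, from 160.1 ± 2.67 to 974 ± 219 CPM (adjusted p = 2.17e-06). Vegfa rose by 0.62 and Pdk1 by 0.56 on the log2 scale, and Pfkfb4 fell by 0.42.

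Members behind small counts that the naming rule did not reach were looked up after their values were seen. Sprr2a2 rose, Sprr2i, Sprr1a and Sprr1b fell, and Sprr2h, Sprr2d, Sprr2j-ps, Sprr2g and Sprr2k did not pass in the Sprr list. Plbd1 was the lipid barrier gene that rose, and Fa2h, Tchh of the cornified list, and Serpinb2 and Ly6d of the spinous list did not pass. Nectin4 and Afdn were the lower junction genes and Prkcz, Cldn12 and F11r the higher tight junction genes. Anxa8, Muc1 and Sfn rose and Krt17, Cldn6 and Wnt6 did not pass in the periderm list. The basal members that did not pass were Lamc2, Lamb3, Itga3, Igfbp3 and Itgb1, and those of the alarm list were Ptgs2, Areg, Sprr2h, Sprr2d and Stfa2. Stat2 and Isg15 fell in the interferon list, Irf1 rose in the family list, and Maml1 rose while Hes5, Lfng and Rbpj fell in the Notch list. Krt75 and Sox9 were the higher hair follicle genes, and Fos, Junb and Fosb rose among the immediate early genes. Sox2, Atoh1, Krt20 and Pou4f3 did not pass among the Merkel genes, nor did Kdm5d and Uty among the sex-linked genes.

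Of the 134 genes named by the rule 124 passed, and in 123 of these every Irf6_KO library lay on the same side of every WT library, the exception being Piezo2. The rule asked for this in the 12 largest rises and 12 largest falls, and chose most others by a small adjusted p. These counts therefore largely follow from the choice of genes. Over all genes tested, 47.9% had no overlap between the groups' libraries. Over the 32 lists, 12 passed by camera with the preset correlation and 0 with an estimated correlation (4 at an unadjusted p under 0.05), while fry gave 15 in one direction and 25 in either direction. Counts adjusted over the list alone equalled those over all genes tested in 18 lists and are given above for the other 14. Coordinates of 6 of the named genes on GRCm38 were chromosome 3, 92080271 to 92083142 for Lor, chromosome 3, 93319749 to 93333570 for Hrnr, chromosome 3, 92823074 to 92827247 for Kprp, chromosome 15, 101858731 to 101869705 for Krt77, chromosome 11, 100203162 to 100207548 for Krt14 and chromosome 15, 101676023 to 101680287 for Krt6b.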

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

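In the 14 alternatives compared gene by gene no shared call had opposite signs, and no list past its threshold changed direction in the 8 alternatives in which camera was rerun with the preset correlation. The test against a fold of 1.5 and the surrogate variable gave counts alone. DESeq2 called 5418 genes, 5126 of them among the 5946 reported, limma-voom 5924 (5841 shared) and edgeR with RLE factors 5699 (5492 shared). A test against a fold of 1.5 left 1584 genes, 435 higher and 1149 lower, because it asks for a larger change. Library size as the only scaling gave 4848 higher genes, since it moves the median log2 fold change up by 0.11. With each library left out in turn, 4397 to 5895 genes changed, and the ranges were 1959 to 2865 for higher and 2438 to 3141 for lower genes, with fewer samples in each fit. A surrogate variable left 5772 genes, no low-count filter 6089, the filter at 1 CPM 5686, no robust estimation 5923, and omission of sex-linked, muscle and erythroid genes 5910. The log2 fold change of Irf6 lay between -2.24 and -1.87 in the 14 alternatives in which it was recomputed, which exclude the test against a fold of 1.5 and the surrogate variable. Of the list tests, 0 passed with an estimated correlation (4 at an unadjusted p under 0.05) against 12 with the preset one, while 25 passed with fry in either direction, which compares a list with no other genes. For the 12 lists the estimated correlations ran from 0.0032 (hair follicle) to 0.716 (cholesterol synthesis), against the preset 0.01. The hair follicle list, whose value was below the preset, was lost as well, so a higher correlation among its own members was not the reason. With an estimated correlation camera also takes its p from the residual degrees of freedom of the 6 libraries, and not from the number of genes. That leaves little power, so a list that did not pass in this version is not shown to be unchanged. How far the higher correlations account for the loss of the other calls was not tested.

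Among the values of named genes under the alternatives, 1802 kept their direction and side of the threshold, 42 no longer passed and 5 newly passed. Of 256 camera tests of single lists under the 8 alternatives, 253 kept their side of the threshold, 1 was lost (hypoxia) and 2 were gained (periderm and adipocyte). The estimated correlation ended 12 calls. By fry in one direction 2 lists passing by camera did not pass and 5 others passed, and by fry in either direction 13 others passed, which are tests of another question. Further, 97 counts of list members moved by over 1.5 times while 821 did not. The cause of these moves was not tested. Leaving out the low-count filter changed the muscle list from 24 to 13 lower members. In simulated data of this depth and spread 66% of genes changed 1.5-fold were recovered. That simulation changed 200 genes, against 5946 called here, which makes the adjusted threshold stricter, so its share does not carry over. A gene that did not pass could still differ by that much, with a chance that was not measured. No paired analysis was possible because the labels give no litter or batch that links a WT with an Irf6_KO sample.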

Other observations

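The test of scaling for the muscle genes and the grouping of genes by symbol stem were chosen only after the results were seen. Genes named here were chosen after their values were seen, except where the rule also named them. Among 509 symbol families with at least 5 tested members, 7 of 1018 tests (Fisher's exact test, one-sided, each direction, against the other named genes tested) passed Benjamini-Hochberg adjustment. The Skint family, whose genes encode butyrophilin-like proteins, had 10 of 11 members lower (adjusted p = 0.000181, median log2 fold change -3.92). Skint6 fell from 34.7 ± 6.42 to 0.844 ± 0.178 CPM and Skint3 from 61.0 ± 10.1 to 4.05 ± 2.32 CPM. Skint9 and Skint5 had no counts in Irf6_KO (at least 140-fold and at least 70.7-fold lower), and Skint7 did not pass (adjusted p = 0.0519). Skint1, known to act in the selection of epidermal T cells, had the smallest fall of the 10, with a log2 fold change of -0.74 (adjusted p = 0.0178). Of 9 kallikrein genes with the stem Klk, serine proteases of which several act in shedding of the outer epidermis, 7 fell (adjusted p = 0.0308). Klk7 fell from 523 ± 65.5 to 1.85 ± 1.43 CPM and Klk5 from 157 ± 5.89 to 1.19 ± 0.669 CPM, while Klk13 and Klk6 did not pass (adjusted p = 0.495 and 0.554).

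The transcription factor genes with the stem Tfap, the AP-2 genes and Tfap4, rose in 5 of 5 cases (adjusted p = 0.0308, median log2 fold change 0.47), Tfap2c by 0.94 and Tfap2a by 0.77. Keratin genes changed both ways, with 19 of 37 lower (adjusted p = 0.00166) and 9 higher, among them Krt14, Krt5 and Krt6b, and 9 that did not pass. Lce genes fell in 18 of 18 cases (adjusted p = 4.55e-11). Genes with the stem Hspb, mostly small heat shock protein genes of which several are known to be expressed in muscle, fell in 6 of 7 cases (adjusted p = 0.0308, median -0.80). The skeletal muscle list had a median of -0.83, with 24 of 24 genes lower. Hspb1 changed by -1.02, Hspb2 by -0.80 and Hspb7 by -0.87 on the log2 scale, and Hspb11, which shares only the symbol stem, did not pass (adjusted p = 0.414). Proteasome ATPase genes fell slightly in 6 of 7 cases (adjusted p = 0.0308, median -0.26), Psmc5 from 208 ± 2.55 to 147 ± 9.20 CPM, and Psmc3ip, which shares only the symbol stem, did not pass. With library size as the only scaling 2 Psmc genes and 11 Skint genes were lower, while the counts of the other families were the same under both other scalings, and no family median changed sign.

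All 24 tested genes of the muscle list were lower in Irf6_KO. Scaling as the whole cause is argued against, since the list's median was at most -0.73 under the other scalings. A smaller share of muscle in the Irf6_KO samples is left possible by an interquartile range of 0.229 over the members' log2 fold changes. That lay within the 0.5 foreseen for 1 factor common to all genes of a cell type. A range this narrow does not, however, separate a smaller share from a joint change of the genes. The cholesterol synthesis list, a pathway and not a cell type, fell with close quartiles too (-0.63 to -0.24). Less mature muscle stays open. Genes of progenitors (14 genes, median -0.64) lay 0.198 above those of mature fibers (16 genes, median -0.84). This difference was under the 0.5 foreseen for that cause and under the 0.25 foreseen without it. It was left open because the bootstrap interval of 0.00452 to 0.388 reached past the latter. The permutation p was 0.00971 (100000 resamples, two-sided). Both resample genes as if independent, although the estimated correlation within the muscle list was 0.608. They thus measure the spread between genes, not between samples, and can be too narrow. Whether dissection or the genotype set any difference in the share of muscle was not tested.

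The knockouts all differed from one another, and replicates 2 and 3 lay apart on the third component (-27.6 and 25.8). Irf6_KO replicate 1 lay apart from replicates 2 and 3 on the second, with 129 genes that separated it, 124 of them lower. Gene dosage on the sex chromosomes is argued against as the main source, since 6 of these genes (4.65%, exact Clopper-Pearson 95% interval 1.73 to 9.85%) lay on X or Y against 3.64% of all tested genes, although its Xist count was 73367. The mitochondrial share was higher in every Irf6_KO library than in every WT library (1.18 to 1.19%), so it followed genotype too. In replicate 1 it was 1.74%, above every other library (at most 1.44%), while that replicate's total count lay within their range. RNA quality may thus contribute to the place of replicate 1, and may also bear on the comparison of genotypes. A smaller share of epidermis cannot be told apart, because its median log2 difference from the other knockouts was -0.273 over the basal list against -0.77 over the alarm genes that rose, less than foreseen for that cause and more than foreseen without it, and the other lists differed in direction (desmosome -0.43, dermal fibroblast 0.24, skeletal muscle -0.30).

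Of the 10 splits of the 6 libraries into 3 and 3, 1 split gave 5946 changed genes, the real one, and the highest of the others gave 0 (505 at an unadjusted p under 0.05, against 7641), with 10 splits being too few for a share under 0.05. Every other split mixes WT and Irf6_KO libraries in both groups, so the genotype difference enters the spread within groups. Their 0 was thus nearly set in advance and does not measure how many calls are false.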
